A study of Arabidopsis thaliana with 6 samples.

How the data were processed

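ChIP-seq libraries from shoot apices of 2 transgenic Arabidopsis thaliana lines were analysed, 3 libraries of gSOC1-GFP and 3 of untagged gSOC1, both in the soc1-2 mutant background. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, material was collected at zeitgeber time 4, chromatin was precipitated with an anti-GFP antibody, fragments of 150 to 400 bp were isolated, and libraries were amplified for 18 PCR cycles and sequenced on a Genome Analyzer II. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values across libraries measure only the spread between these samples, which may be technical.

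The authors deposited 1 table of 24032 regions, with a text that defines its columns. The deposited read count of each region and library was not normalized, per the file headers and column definitions. The authors' p-value column was a Benjamini-Hochberg q-value (FDR) for each replicate, which set the tagged against the control library of that number, per the column definitions deposited with the table. The same pair of counts had more than 1 FDR in 1366 of 4382 distinct pairs of replicate 1, so the authors' test used more than these counts, and the test itself is not given in the sources used here. The authors' log2 column was the log2 rank product over the 3 replicates, per the column definitions. Recomputed from the ranks of the FDR values, it had a Spearman correlation of 1.00 with the deposited column. The authors' rank score ordered the regions by this product, per the column definitions, and was used only to order regions within the table. The genome was TAIR10, per the submitters' processing notes. The aligner, the region caller and the read filters are not given in the sources used here. Starts are printed as deposited, and whether they count from 0 or 1 is not given in the sources used here; ends were computed from start and length. Region identifiers ran to 29948, so the table may hold part of a longer list. The 5 mitochondrial regions held no called region.

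A region was called where the authors' FDR was below 0.05 in all 3 replicates. The design written before the data were examined had assumed a combined FDR, and this rule replaced it once the columns were known. Genes were assigned from the authors' columns where the region's centre overlapped a gene, or lay up to 3 kb upstream or 1 kb downstream of a flanking gene by its strand. Gene symbols came from the RefSeq gene table, used only for names and gene types, in which 22586 of the 22909 assigned genes (98.6%) were found. Log2 enrichment was the difference in log2 scaled counts of a replicate pair, with TMM effective library sizes and a prior count of 1 scaled to library size, and is given as mean ± SD over 3 pairs. The prior count pulls regions with few reads toward no enrichment, but an untagged count of 0 can still raise the mean. Such a count occurred in at least 1 library at 57 called regions. At each list member's region with one, the mean lay above the log2 fold change of edgeR with a replicate block. Examples are SHP2 (6.10 against 5.28) and AGL18 (4.70 against 3.81).

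Tagged and untagged counts were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, without a replicate block, with Benjamini-Hochberg adjustment over 24032 regions. DESeq2 1.42.0 was an alternative, in which 5822 regions received an adjusted p. The replicate numbers were checked for pairing before the calls were compared. Deviations from the group means in the same-numbered tagged and untagged libraries correlated at 0.498, 0.123 and 0.139 for replicates 1, 2 and 3. Each exceeded the bound of 0.1 set for pairing, so the numbers were taken to pair the samples. Replicates 2 and 3 exceeded it narrowly, and gSOC1-GFP replicate 3 with untagged replicate 2, which differ in number, correlated at 0.131, above the pair of replicate 2. Deviations from a group mean cancel out within the group. Replicate 1 correlated negatively with the other numbers, from -0.293 to -0.215, which by itself pushes the correlations among replicates 2 and 3 upward. The bound therefore tells little of pairing in replicates 2 and 3. The pairing comes from the replicate numbers in the titles, and the deposited FDR columns set the same numbers against each other. The common biological coefficient of variation was 0.554 without the replicate block and 0.362 with it, and the block changed the number of calls from 0 to 91. The edgeR procedure was tested on simulated data for this comparison, with 200 of the 24032 regions changed. Counts were drawn with pair-specific means and the dispersion of the fit with the block. The simulation thus took the pairing as given and favoured the block, and it cannot show that the pairing is real. Without the block it recovered 0% of the regions changed 4, 8, 16 or 32-fold. With the block it recovered 50%, 94%, 98% and 100%, with 3 false calls. The list test was tested on 200 simulated lists, where it recovered 100% of planted lists and called 2.5% of random ones. The planted lists held genes drawn from those with a called region and were scored against the same genes. Their recovery was thus largely fixed by construction. It says little about weaker excesses or about neighbouring genes that share a region.

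The 14 gene lists, 4 of them for comparison, and the 10 families were fixed before the data were examined. Each was tested with a two-sided Fisher's exact test against 27444 nuclear protein-coding genes, of which 376 had a called region, with Benjamini-Hochberg adjustment over lists or over families. Families were recognised by gene names in the RefSeq table, which can include genes named after a partner and misses members named otherwise, such as AP3 of the MADS family, SUP of the zinc finger family and ALC of the bHLH family, all of which had a called region. Position was tested with 10000 draws of uncalled regions from the same table, over 9 classes. Python 3.11.15, SciPy 1.17.1, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used. The named genes were SOC1, the genes at the 10 top-ranked called regions, and members of the first 10 lists with a called region, up to 25 by rank; any comparison list member with a called region would have been named. For the 10 top-ranked regions shared by several genes the one with the nearest start is given first; under the lists a region is described by its list member, and a gene with a nearer start is named beside it.

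The median count per region was 15, 5 and 8 in gSOC1-GFP replicates 1, 2 and 3 and 6, 1 and 2 in the untagged replicates, so single untagged counts of replicates 2 and 3 carry little precision. The share of reads in called regions had 95% exact binomial (Clopper-Pearson) intervals of 8.20% to 8.33% in gSOC1-GFP replicate 1, the deepest library, and 1.62% to 1.87% in untagged replicate 2, the shallowest. PCR reads without molecular identifiers are not independent molecules, so such intervals cover counting error only. Alternatives covered the FDR threshold, the replicates used, the block, DESeq2, scaling by library totals, a filter on low counts, the prior count, the gene window and the background. The CArG motif and random genome positions were not analysed here, because they need the genome sequence.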

Results

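Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where SOC1, a MADS-domain transcription factor that promotes flowering, bound the Arabidopsis thaliana genome. Shoot apices came from soc1-2 mutant plants carrying either a genomic SOC1 copy fused to GFP (gSOC1-GFP, line 7) or the same genomic copy without GFP (untagged gSOC1, line 9). Plants grew for 15 short days and then 3 long days and were collected 4 hours after lights-on. Chromatin of both genotypes was precipitated with an antibody against GFP, so that the untagged libraries measured the background. Each genotype had 3 libraries, and the deposited table gave the read count of each library in 24032 candidate regions with a median length of 212 bp. The gSOC1-GFP libraries held 663108, 183668 and 262776 reads in these regions for replicates 1, 2 and 3. The untagged libraries held 396326, 41073 and 61963 reads, and the total depth of the libraries was not used here.

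The comparison of tagged with untagged chromatin asked which regions SOC1-GFP occupied at the apex. In all 3 replicates 270 regions passed the authors' false discovery rate (FDR) of 0.05, and these are referred to as called regions. Of these, 18 had no gene within the windows used and 151 were assigned to 2 or more genes. The assigned genes numbered 400. Among them were SOC1 itself, the floral repressors AGL15, AGL18 and, at the weakest of the named regions, SVP, and the floral organ identity genes AP3 and SEP3. The median called region had a mean log2 enrichment of 2.43 over the untagged libraries (5.38-fold; median SD 0.83, n = 3 pairs), against 0.30 for the other regions. With a prior count of 10 in place of 1 the median of the called regions was 1.52. With counts scaled to the TMM library sizes, the log2 enrichment was above 0 in all 3 pairs at 258 of the 270 regions, which had been chosen on the FDR of these pairs. Called regions took 9.40% ± 1.72 (SD, n = 3) of the listed reads in the gSOC1-GFP libraries and 1.62% ± 0.16 (SD, n = 3) in the untagged libraries. The exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries allow, and the regions had been chosen on this difference.

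**Figure D1:**
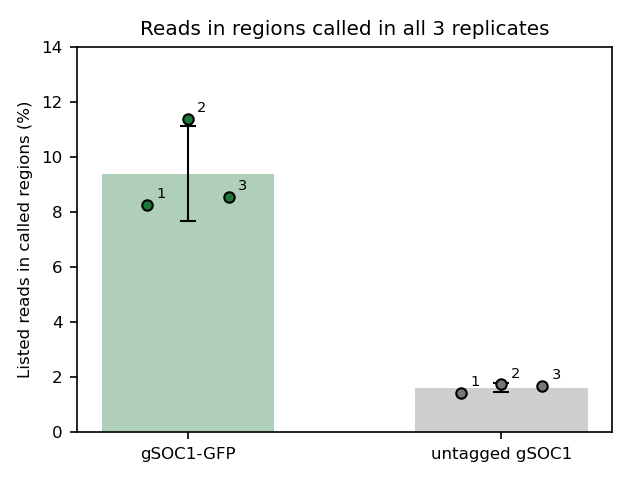
Share of each library's listed reads (percent, vertical axis) that fell in the 270 called regions, for gSOC1-GFP and untagged gSOC1. Bars are means, error bars are SD over 3 libraries, and points are libraries numbered by replicate; the gSOC1-GFP libraries lie between 8.26% and 11.4% and the untagged libraries between 1.44% and 1.74%.

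In regions whose FDR filter left out the replicate that was measured, the enrichment was also present. The candidate regions themselves came from the deposited table, which may have drawn on all 3 replicates. The 295 regions past the FDR in replicates 2 and 3 had a median log2 enrichment of 2.04 in replicate 1, where 88.8% lay above 0. The 407 regions past it in replicates 1 and 3 had a median of 2.15 in replicate 2, where 93.6% lay above 0. For the 468 regions past it in replicates 1 and 2 the median was 1.56 in replicate 3, where 90.6% lay above 0. The remaining regions had medians of -0.08, 0.46 and 0.37 in replicates 1, 2 and 3, and 47.8%, 63.1% and 60.9% of them lay above 0. Among the 270 top regions of each replicate, replicates 1 and 2 shared 179, replicates 1 and 3 shared 173 and replicates 2 and 3 shared 170, where independent lists would share 3.03. Across all listed regions, which are not independent replicates, Spearman's rho of the authors' significance between replicates was 0.06 for replicates 1 and 2, 0.03 for replicates 1 and 3 and 0.03 for replicates 2 and 3. Over the same regions Pearson's r of the log2 scores was 0.533, 0.454 and 0.492 for these pairs, and within the called regions Spearman's rho was 0.754, 0.786 and 0.788.

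The number of single regions that passed a test across the libraries differed with the tool, the replicate block and the libraries used. Without the block, edgeR called 0 regions after Benjamini-Hochberg adjustment, with 762 at an unadjusted p under 0.05. In the simulation, which favoured the block, this fit recovered 0% of the regions changed 32-fold. Its 0 calls, here and under the lists below, therefore say little about single regions. DESeq2, which also changed the scaling and gave 5822 regions an adjusted p, called 94. With the replicate number as a block, edgeR called 91 regions, all of them higher in gSOC1-GFP, and 82 of these were among the 270 called regions. Without the block and without both replicate 1 libraries edgeR called 86 regions, and without the untagged library of replicate 1 alone it called 51, of which 50 were higher and 1 was lower in gSOC1-GFP. Leaving out the gSOC1-GFP library of replicate 2 or that of replicate 3 gave 1 region each.

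The top-ranked region lay 89 bp upstream of SOC1 (AT2G45660) on chromosome 2, from 18810951 to 18811322 in TAIR10 coordinates. It held 2018, 808 and 1038 reads in the gSOC1-GFP libraries and 74, 5 and 18 in the untagged libraries, a mean log2 enrichment of 4.37 ± 1.00 (SD, n = 3). A second called region 1975 bp upstream of SOC1, of rank 30, had a log2 enrichment of 2.41 ± 0.50 (SD, n = 3). The region of rank 2 lay 273 bp upstream of ATG18C, a gene of the autophagy family, on chromosome 2 from 17032006 to 17032375, with a log2 enrichment of 5.69 ± 1.61 (SD, n = 3). The region of rank 3 lay in the 5' UTR of AT5G58900 (4.94 ± 0.45) and that of rank 4 lay 228 bp upstream of AT5G21280 (4.40 ± 0.44). The region of rank 5 lay 2495 bp upstream of LEJ2 (5.50 ± 1.13). The region of rank 6 was shared by RS40, 849 bp away, and CBF1, 996 bp away (3.98 ± 0.23). Rank 7 lay 366 bp downstream of ZF14 (4.89 ± 1.38), and rank 8 was shared by AT1G63950 and MDAR6 (5.29 ± 1.40). Rank 9 lay 256 bp upstream of AT5G44590 (4.47 ± 0.57). The region of rank 10 was shared by TON1A, 2357 bp away, and SMZ, 2628 bp away (4.29 ± 0.36). Each of these 10 regions passed edgeR with the replicate block, at adjusted p from 0.000237 to 0.00937.

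**Figure D2:**
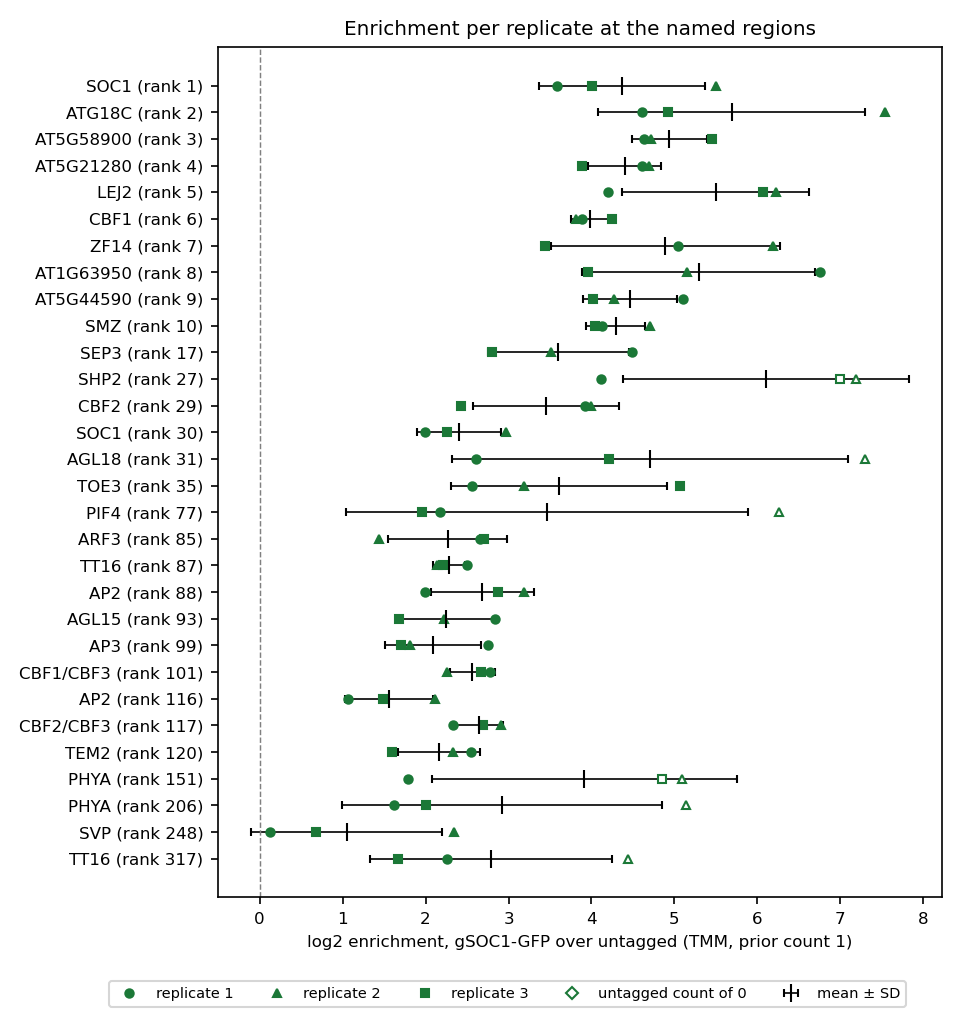
Log2 enrichment of gSOC1-GFP over untagged gSOC1 (horizontal axis, TMM-scaled counts with a prior count of 1) at the 30 named regions, ordered by the authors' rank. Symbols are the 3 replicate pairs, open where the untagged count was 0, and bars are mean ± SD; every mean lies above 0, from 1.05 at SVP (rank 248) to 6.10 at SHP2 (rank 27), whose untagged count was 0 in 2 pairs and whose mean was 8.36 with a prior count of 0.1 and 3.64 with 10.

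Genes that delay flowering carried called regions more often than other genes did. Of 19 listed flowering repressors, 7 had a called region against 0.26 expected (two-sided Fisher's exact test, adjusted p = 5.25e-08). With genes assigned only up to 1 kb upstream, 2 of 19 had one against 0.138 expected (adjusted p = 0.0385), and without replicate 3 the ratio to the expected number was 15.6 in place of 26.9. The 7 genes were the MADS-domain genes SVP, AGL15 and AGL18, the AP2-type genes SMZ, TOE3 and AP2, and TEM2, a repressor of FT. The region 86 bp upstream of AGL18 held 325, 128 and 151 tagged reads against 23, 0 and 2 untagged reads. The region 1377 bp upstream of TOE3 held 276, 131 and 157 tagged reads against 20, 4 and 1 untagged reads. The region 234 bp upstream of AGL15 had a log2 enrichment of 2.25 ± 0.58 (SD, n = 3) and that 2627 bp upstream of TEM2, shared with the nearer STN7, one of 2.16 ± 0.50. AP2 had called regions 1653 bp and 2838 bp upstream, at 2.68 ± 0.62 and 1.56 ± 0.53. The region 2248 bp upstream of SVP, which lay only 184 bp upstream of AT2G22530, was the lowest of the group, at 1.05 ± 1.15, with 110 tagged and 45 untagged reads in replicate 1, and its mean was 0.40 without replicate 2. With the replicate block, edgeR called regions of 3 repressors over all regions (AGL18, SMZ and TOE3) and of 8 adjusted over the list alone, against 0 and 0 without the block.

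Floral organ identity genes of the MADS family also carried more called regions than expected, 4 of 12 against 0.164 (two-sided Fisher's exact test, adjusted p = 0.00011), and without replicate 3 the ratio to the expected number was 14.1 in place of 24.3. The genes were AP3, a petal and stamen identity gene, SEP3, a cofactor of the floral organ complexes, SHP2, an ovule and fruit gene, and TT16, which acts in the seed coat. The region 374 bp upstream of SHP2 held 348, 119 and 155 tagged reads and 8, 0 and 0 untagged reads. The region 2725 bp upstream of SEP3, which lay 1634 bp upstream of AT1G24265, had a log2 enrichment of 3.60 ± 0.85 (SD, n = 3), and that 146 bp upstream of AP3 one of 2.09 ± 0.58. TT16 had called regions 2661 bp and 737 bp upstream, at 2.28 ± 0.19 and 2.79 ± 1.46. edgeR with the block called regions of 2 members over all regions, SEP3 and SHP2, and of 5 adjusted over the list alone; without the block these numbers were 0 and 2.

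Of 14 cold response genes 3 had a called region, against 0.192 expected (two-sided Fisher's exact test, adjusted p = 0.00387). All 3 were the tandem genes CBF1, CBF2 and CBF3, activators of cold-induced genes, and some regions were shared between neighbours. Counted as 1 locus they gave an adjusted p of 0.418, so the excess among the called regions rested on this cluster. Without replicate 3 the ratio to the expected number was 9.08 in place of 15.6. Without replicate 2 it was 17.6, with 5 of 14 members (adjusted Fisher p = 2.74e-05). The members gained were KIN1 and KIN2, which share 1 region, and this setting was not tested with the CBF genes as 1 locus. The region over the 3' UTR of CBF2 had a log2 enrichment of 3.45 ± 0.88 (SD, n = 3), the region between CBF1 and CBF3 one of 2.56 ± 0.27 and that between CBF2 and CBF3 one of 2.64 ± 0.29. edgeR with the block called regions of CBF1 and CBF2 over all regions and of 3 members adjusted over the list alone, against 0 and 0 without the block.

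The other lists did not pass the test with the FDR and windows used for the called regions. Of 24 photoperiod, light and clock genes 2 had called regions, the photoreceptor gene PHYA and the growth regulator PIF4 (two-sided Fisher's exact test, adjusted p = 0.148). This list passed with genes assigned only up to 1 kb upstream (adjusted p = 0.0455) and at an FDR of 0.1, where 3 members had a region (adjusted p = 0.0322). PHYA had called regions 518 bp and 92 bp upstream, with 91, 27 and 34 tagged reads against 11, 0 and 0 untagged reads in the first of these. The region over the 5' UTR of PIF4 held 180, 62 and 85 tagged reads against 17, 0 and 6 untagged reads. The auxin list had 1 of 17 members, ARF3, with a log2 enrichment of 2.27 ± 0.72 (SD, n = 3) at 2406 bp upstream. SOC1 was the single member with a called region among 15 floral integrators and among 6 genes of its own family. No called region was assigned to the 24 gibberellin genes, the 24 shoot meristem and polarity genes or the 8 protein-coding genes of the SPL and miR156 module. The microRNA genes of that list were outside the background tested. MIR156e, a miR156 gene that was not on the list, had a called region of rank 14. Without replicate 3, the gibberellin list had 4 members with a region and an adjusted Fisher p of 0.0105. The 10 shoot and flowering lists together had 18 of 162 genes with a called region against 2.22 expected. The 4 comparison lists, which covered photosynthesis, seed storage, housekeeping and root genes, had 0 of 44 against 0.603 expected. With so small an expected number a count of 0 is likely for random genes too, so these lists say little as a contrast. edgeR with the block, adjusted over the list alone, called regions of 2 photoperiod genes, 2 SOC1 family genes and 1 integrator, against 0, 1 and 1 over all regions. Without the block it called 1 SOC1 family gene adjusted over the list alone and 0 over all regions.

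**Figure D3:**
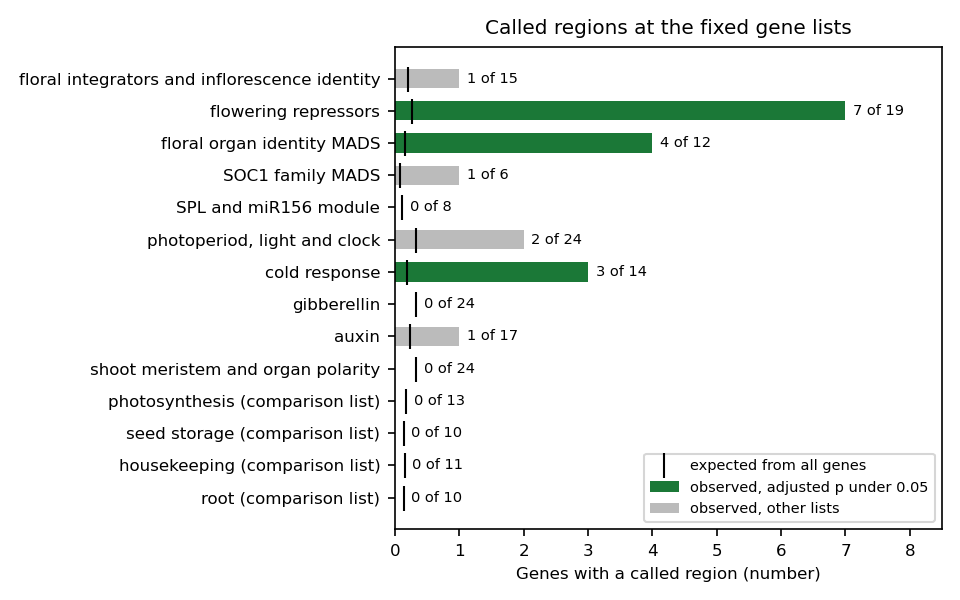
Number of genes with a called region (horizontal axis) in each of the 14 gene lists, with the members tested printed at the right of each bar. Green bars passed an adjusted p of 0.05, gray bars did not, and vertical ticks mark the number expected from all protein-coding genes. Flowering repressors reached 7 of 19, and the 4 comparison lists reached 0, against only 0.603 expected over these lists together.

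Among transcription factor families recognised by gene name, AP2/ERF genes and MADS genes carried more called regions than expected. A gene whose name does not show its family was not counted, and a gene named after a partner could be. The counts, the MYB and zinc finger counts included, are therefore not totals of the families and may hold genes that are not members. The AP2/ERF family had 9 of 78 genes against 1.07 expected (two-sided Fisher's exact test, adjusted p = 1.23e-05), with EDF3 and AT5G07310 beside the repressors and CBF genes above. CBF1, CBF2 and CBF3 were counted singly here, and the family test was not repeated with them as 1 locus. In both families most genes with a called region were also members of the lists above, so the family tests largely repeat the list tests. The MADS family had 8 of 101 genes against 1.38 expected (adjusted p = 0.000384), which left out AP3 by its name and included AT1G30260; without replicate 3 the ratio to the expected number was 3.35 in place of 5.78. With genes assigned only up to 1 kb upstream, the AP2/ERF family had an adjusted p of 0.55, and without replicate 3 its ratio to the expected number was 5.43 in place of 8.42. The MYB family had 3 of 147 genes (adjusted p = 0.763), and it passed the test without replicate 3 (adjusted p = 0.0278) and among the regions called by edgeR with the block (adjusted p = 0.0098). The bHLH, homeobox, NAC, WRKY, zinc finger, auxin response and SPL families, with 2, 0, 3, 1, 2, 1 and 0 genes recognised by name, did not pass.

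Called regions lay outside coding sequence more often than the other listed regions did. Their centres fell in a coding exon in 2.22% of called and 10.2% of other regions (two-sided permutation test with 10000 draws, adjusted p = 0.0018). The centre lay within a gene in 19.6% of called and 31.3% of other regions (two-sided Fisher's exact test, p = 2.15e-05). Any part of the region overlapped a gene in 48.5% of called and 55.3% of other regions (two-sided Fisher's exact test, p = 0.0268). Up to 1 kb upstream of a gene lay 47.0% of called and 42.7% of other regions (adjusted p = 0.335), and the shares of the other 7 classes also did not pass the test. Among the 91 regions called by edgeR with the block, 3.30% had their centre in a coding exon, against 10.2% of the other regions, a difference of -6.89 percentage points (adjusted p = 0.296) beside -7.97 for the 270 called regions.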

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

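The tests chosen after the results were seen were those with regions past the FDR in at least 2 replicates, library totals, the block combined with a filter, with totals or with a replicate left out, lists, families and positions from the regions edgeR called with the block, and the CBF genes as 1 locus. The cause of the changes below was not tested unless stated. The number of called regions was 182 at an FDR of 0.01 and 363 at 0.1, it ranged from 295 to 468 when each replicate was left out, which asks for fewer replicates by construction, and it was 630 with at least 2 replicates.

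The number of regions edgeR called moved from 0 to 91 with the replicate block. DESeq2 without the block, which also changed the scaling and gave 5822 regions an adjusted p, called 94. The edgeR number was 120 with the filter and the block, 18 with library totals, and 211 with library totals and the block. With libraries or replicates left out it ranged from 0 to 86 (without replicate 1) without the block, and it was 71, 119 and 69 with the block and without replicate 1, 2 and 3. Where the 91 regions edgeR called with the replicate block took the place of the 270, which changes the caller, the block and the number of regions together, coding exons no longer passed at a difference of -6.89 percentage points (adjusted p = 0.296) and the MYB family passed (6.79 times the expected number). No other call of a list, family or position class changed.

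The median log2 enrichment of called regions was 1.52 with a prior count of 10, which shrinks regions with few reads by construction, and 2.69 with 0.1. Of 150 values for 30 named regions under alternatives, 0 changed sign and 16 moved by 1 SD or more. All 30 had been chosen for passing the FDR in every replicate, so a change of sign was unlikely in advance. Between replicates 1 and 2, 1 and 3, and 2 and 3, Spearman's rho within called regions was 0.754, 0.786 and 0.788, and Pearson's r of the log2 scores was 0.533, 0.454 and 0.492. The number of families past the test was 1 with a 1 kb upstream window. The gibberellin list went from below to above its expected number, to 7.06 times without replicate 3 and 5.27 times with at least 2 replicates. Of the other values for single lists and families under alternatives, 208 kept their side of the threshold, 5 gained a call (photoperiod genes in 2 and the MYB family in 3) and 2 lost one (cold response as 1 locus and AP2/ERF with a 1 kb window).

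The planned CArG motif windows and the background of random genome positions were not run. Depth limits the untagged libraries of replicates 2 and 3, which had 7747 and 4639 of the 24032 regions at 0 reads.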

Other observations

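The genes in this paragraph and the next were chosen after their values were seen. The region of rank 14 lay 1495 bp upstream of MIR156e, a microRNA gene of the family that holds back the juvenile to adult transition, and held 579, 240 and 229 tagged reads against 8, 1 and 0 untagged reads. An intron of SPA2, a partner of the ubiquitin ligase COP1 in light signalling, held the region of rank 15, with a log2 enrichment of 5.11 ± 1.72 (SD, n = 3). FBH4, a bHLH activator of CO, had a region 2486 bp upstream at 3.33 ± 0.13 (SD, n = 3). SUP, a zinc finger gene that sets the boundary between stamens and carpels, had a region 956 bp upstream with 176, 54 and 78 tagged reads against 6, 1 and 0 untagged reads. With the replicate block, edgeR called the regions at MIR156e, SPA2, FBH4 and SUP at adjusted p of 0.000157, 0.000259, 0.00817 and 0.00152.

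The histone acetyltransferase genes HAC1 and HAC5 had called regions of rank 137 and 152, with log2 enrichments of 2.28 ± 1.46 and 1.43 ± 0.47 (SD, n = 3). P5CS1, an enzyme of proline synthesis, had 76, 23 and 29 tagged reads against 2, 1 and 0 untagged reads at a region 2191 bp upstream. GolS2, an enzyme of raffinose synthesis, had a region 503 bp upstream at 2.82 ± 0.75 (SD, n = 3).

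The tests of the SOC1 background, of the list surroundings, of the splits and of the abscisic acid genes were chosen after the results they bear on had been seen; the test of depth was chosen before.

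Untagged reads at 3 called regions upstream of SOC1 exceeded those at most other called regions, with 74, 5 and 18 reads at rank 1, 41, 5 and 17 at rank 30 and 57, 16 and 20 at rank 59, against medians of 12, 2 and 3. The untagged to tagged ratio of the other top-ranked regions set a limit for carry-over of tagged material. At rank 59, 3 of 3 untagged counts exceeded it (13, 6 and 11 reads), so carry-over at that ratio did not by itself account for them. The limit left no room for ordinary background reads, so it cannot decide whether carry-over added reads at rank 59. At rank 1 and 30, 3 of 6 counts exceeded their limits, and carry-over stays open there too. Both lines carry a genomic SOC1 copy by design, and its DNA may also add reads. The lowest of the 3 untagged levels stood at percentile 94.01 of the other called regions (95% interval 87.3 to 96.3). The 13 regions 10 to 40 kb away stood at a median of 80.9 (59.6 to 88.4). These intervals reach across the bounds set at 95 and 75. The 13 regions were uncalled, whereas called regions had been chosen for few untagged reads beside their tagged reads, so the test cannot decide. The copy number in line 7 and in line 9 was not compared, so its effect on the enrichment at SOC1 stays open too. No biological explanation was tested.

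More regions passed the authors' FDR in replicate 1 (2422) than in replicate 2 (687) or 3 (760). Greater depth may account for this. A one-sided binomial test on the counts called 474, 126 and 126 regions in the 3 replicates, and with replicate 1 thinned to the depth of replicate 2 or 3 it called a median of 107 or 171 over 20 thinnings. The binomial test is not the authors' own test, and no biological explanation was tested.

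The excess of called regions at flowering repressors, floral organ identity genes and cold response genes could come from long gene surroundings that collect more listed regions. Random lists matched on the number of uncalled listed regions per gene reached the observed numbers with a one-sided p of at most 0.0002 in 10000 draws. The number of uncalled listed regions thus did not account for the excess. Matching moved the expected numbers of the 3 lists only from 0.260, 0.164 and 0.192 to 0.227, 0.167 and 0.153. The length of the surroundings was not measured, so the test cannot decide on length itself. The hypothesis that these gene groups are preferred targets stays a hypothesis, since the p was computed on the same data and the cold response excess rests on 1 cluster.

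For edgeR without the block the real split of the 6 libraries gave 0 calls, so that 10 of the 10 splits gave as many by construction and the comparison says nothing of chance; the highest other gave 80. The splits with 80 and 62 calls put both replicate 1 libraries on the same side. With the replicate block, 1 of the 4 splits that part every pair, the real one, gave as many as 91 calls and the highest other gave 0. These 4 splits are too few for a share under 0.05.

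A hypothesis was that called regions gather at core abscisic acid signalling genes. Of 26 such genes 4 had a called region against 0.356 expected (two-sided Fisher's exact test, p = 0.000408): ABF4 at 3.66 ± 1.15, ABI5 at 3.47 ± 0.48, PYR1 at 1.92 ± 1.27 and PYL8 at 0.85 ± 0.54 (log2 enrichment, SD, n = 3). The list was written after these 4 names had been seen. They were also all the members with a called region, so that 0 of 22 genes without them, against 0.298 expected, was fixed by leaving them out. The bound set against the hypothesis was thus met by construction. So small an expected number also gives as few in 74.1% of random lists. The data therefore neither bear the hypothesis out nor exclude it.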
